A study of Mus musculus with 6 samples.

How the data were processed

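Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on primary neural stem cells from the cortex of newborn mice, grown in medium with EGF and bFGF, per the labels. Formaldehyde-fixed chromatin was sonicated and libraries were made with a ligation-based kit, per the labels' protocols. There were 6 libraries in 6 groups of 1. In 2 libraries the target was Seh1, a nucleoporin of the Y-shaped complex of the nuclear pore: one with the flag tag in cells titled iKO, and one with Seh1 itself in Ctrl cells. In 4 libraries the target was Chd4, the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex: Ctrl, iKO, siSCR and siSeh1. The iKO cells were treated with 4-hydroxytamoxifen, per the labels. The labels give the genotype mutant for the Chd4 iKO library and wild type for the Seh1-flag library, although its title says iKO, and the header name of its list begins with oe before seh1. Whether tagged Seh1 was overexpressed, and whether the cells' own Seh1 was present, is not given in the sources used here and is left open.

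The deposited files are peak lists annotated with HOMER on mouse build mm10, per the file headers. Bowtie2 and HOMER are named without versions in the submitters' processing notes, which also name human builds in place of the mouse build of the headers and the mouse gene names. The peak caller, its threshold, the input used and any pooling are not given in the sources used here. The names of the annotated lists end in summits for 5 libraries, per the file headers. In these 5 lists each peak is a single position with a deposited peak score, whose scale is not stated. The smallest deposited score was just over 2 in each of them, as a limit of 0.01 on a −log10 p or q scale would leave. The Seh1 Ctrl list holds intervals of 240 to 1296 bp, and all 20833 of its deposited scores are 0, so its peaks have no ranking. The deposited score was used only to rank or select peaks within a list, except in a setting with the same minimum score in both lists of a comparison. That setting assumes a common scale, which is not known. Total tags per library are not in the lists used here, so the depth of each library is unknown.

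The design written before the data were examined assumed intervals in every list. The 5 lists of summits were therefore widened to windows of 240 bp, the most common width in the Seh1 Ctrl list, and peaks were called shared when they overlapped by at least 1 bp. Overlaps were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the code was checked against bedtools 2.31.1, which gave the same 411 overlapping peaks for siSCR in siSeh1. On simulated lists the size of the iKO against Ctrl comparison, all 500 of 500 planted overlaps were recovered. Each overlap was set beside 100 random placements of the same peaks on the same chromosomes, between the outermost peaks of the 6 lists. Random placement describes chance for these libraries and is no test of the conditions. No genome sequence was used, so placements were not matched for base composition or mappability.

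A promoter peak lay within 1 kb of the nearest transcription start site (TSS), by the distance in the deposited annotation. That annotation names only the nearest TSS, so the partner gene of a shared promoter stays unnamed. A gene was called gained when it had a promoter peak in the perturbed list and none in its control list, and lost in the opposite case. Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only. With 1 library per group there are no replicates, so no p-value across conditions is given. Coordinates are those of the files. Gene symbols, gene spans and the background of 21900 protein-coding genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 represents, and 99.9% of the gene identifiers in the lists matched it.

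The genes named were chosen by a rule fixed before the data were examined. It takes the first 10 by mean promoter rank over iKO and siSeh1 among genes gained in both comparisons, the first 10 of these with a promoter peak in either Seh1 list, genes shared by the Chd4 lists of control cells, genes shared by both Seh1 lists, up to 6 members of each of 14 gene lists, and Seh1l, Chd4 and Cdkn1a whatever their values. Ranks of genes shared by the Seh1 lists came from the Seh1-flag list alone. Symbols of predicted and microRNA genes were left out. The 7 genes with a Chd4 promoter peak in Ctrl were named outside this rule, after their values were seen. For each gene list the count of members with a promoter peak was compared with 10000 random lists of the same size. These random lists were not matched for expression or promoter type. Alternatives changed the promoter window, the overlap rule, the score limit, the list length, the chromosomes, the repeats, the background and the random placement.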

Results

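The study asked whether the nucleoporin Seh1 and the chromatin remodeller Chd4 act together on genes in neural stem cells, and what happens to Chd4 on chromatin when Seh1 is removed. Chd4 was profiled in control cells (Ctrl), in cells labelled iKO, of mutant genotype and treated with 4-hydroxytamoxifen, and in cells labelled siSCR and siSeh1. The labels do not spell these names out; iKO is read here as deletion of Seh1, siSeh1 as its silencing and siSCR as the control of the silencing. Seh1 was profiled through a flag tag (Seh1-flag) and with Seh1 as the target in Ctrl cells (Seh1 Ctrl). The labels and the file header leave open whether the tagged Seh1 was overexpressed, which bears on every Seh1-flag value. Each group had 1 library, so every difference below is between 2 libraries and has no replicate check. The Seh1-flag list held 24961 peaks and the Seh1 Ctrl list 20833. The Chd4 lists held 1154 peaks in Ctrl, 21294 in iKO, 2606 in siSCR and 26935 in siSeh1. Total tags per library are not in these lists, so the depth behind each list is unknown, and intervals cover counting error only. Peak scores are the authors' and are compared only within a list, except in a setting that put the same minimum score on both lists of a comparison.

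**Figure D1:**
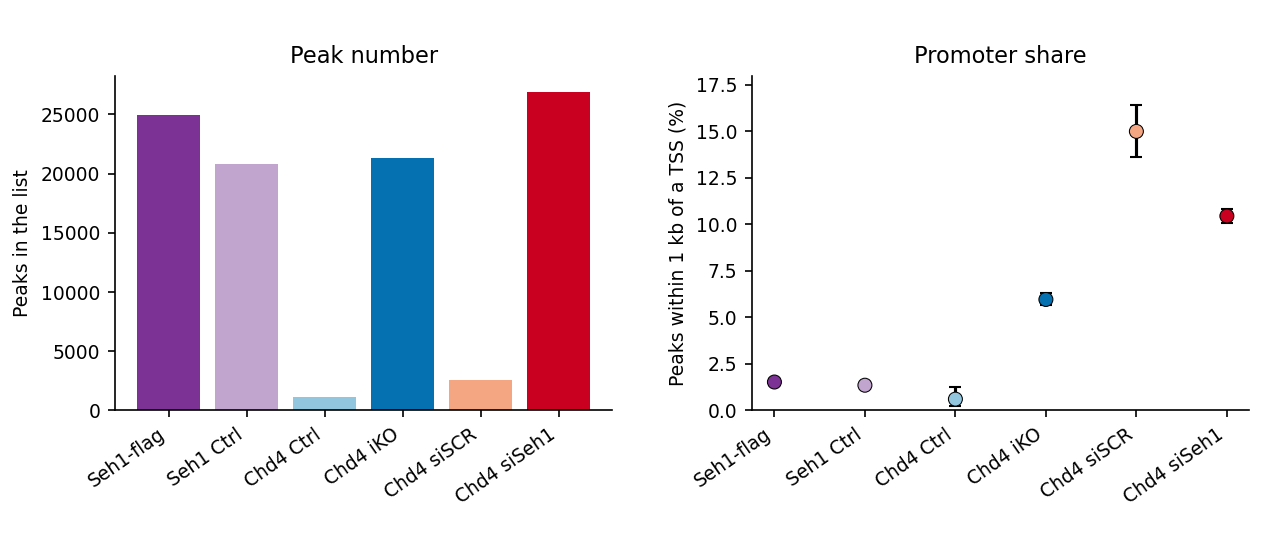
Number of peaks in each list (left, bars) and percent of peaks within 1 kb of a TSS (right, points with exact 95% intervals, counting error only), for 1 library per group. The iKO and siSeh1 lists of Chd4 hold 21294 and 26935 peaks against 1154 and 2606 in their controls.

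The targeted genes were looked at first. Seh1l, which encodes Seh1 (chromosome 18, 67774876 to 67795487), had no promoter peak in any of the 6 lists. A peak in exon 4 of its 8 exons was listed for Seh1-flag, Seh1 Ctrl, siSCR and siSeh1, and siSeh1 also had peaks in exons 3 and 7. Peak lists do not show whether the gene was deleted or silenced, so they leave the labels unchecked. Chd4 itself (chromosome 6, 125095980 to 125130591) had no promoter peak either. Its exons held 6 peaks in siSCR, 7 in siSeh1, 2 in iKO and 0 in Ctrl, and its introns held 1, 1, 0 and 0.

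**Figure D2:**
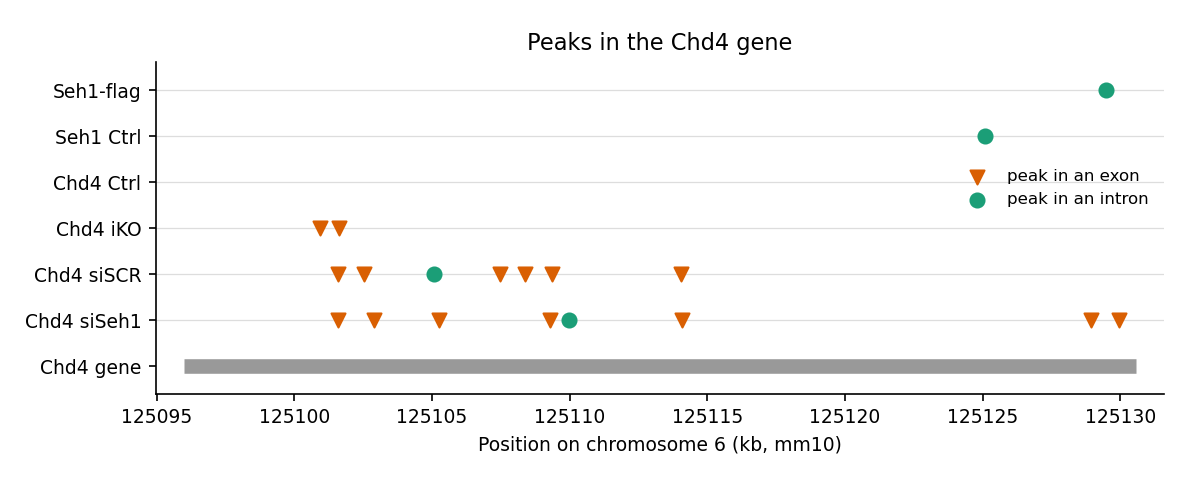
Peaks in the Chd4 gene by library, on chromosome 6 of mm10 (kb). Triangles are peaks annotated to an exon, circles peaks annotated to an intron, and the grey bar is the gene. Of the 7 peaks in siSCR 6 lie in exons, and of the 8 in siSeh1 7 do.

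Cdkn1a, the cyclin-dependent kinase inhibitor p21, had no peak inside the gene (chromosome 17, 29090979 to 29100722) in any list. The nearest peak lay in intergenic sequence 2262 bp beyond the 3' end in Seh1-flag (position 29102984), 2312 bp beyond it in Chd4 Ctrl and 2223 bp beyond it in siSCR. These 3 peaks, at 29102984, 29103034 and 29102945, lay close together in a region dense in peaks, 29000001 to 29200000. That region held 11 Seh1-flag, 5 Chd4 Ctrl and 4 siSCR peaks, 2 in siSeh1 and 0 in iKO. Whether its density accounts for the 3 peaks was not tested. In iKO the nearest peak was 148275 bp away, in siSeh1 78038 bp and in Seh1 Ctrl 466844 bp.

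Deletion of Seh1 was compared with Ctrl. In the iKO list Chd4 was listed at the promoters of 1245 genes, and none of these had a Chd4 promoter peak in Ctrl. They included Ezh2, the methyltransferase of Polycomb repressive complex 2, with a peak score of 11.2 on chromosome 6 at 47595169. Smarca2, an ATPase of the BAF remodeller, and Bub1, a mitotic checkpoint kinase, each had a score of 9.38. Gatad2a and Mbd3, both NuRD subunits, had scores of 9.48 and 5.60. Ezh2, Gatad2a and Mbd3 also had a Chd4 promoter peak in the control siSCR. The median score of the iKO promoter genes was 4.74 in a list whose median over all peaks was 3.39.

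The 7 genes with a Chd4 promoter peak in Ctrl were Tmem181b-ps, LOC108168459, Tmem254b, Sec14l3, Mageb18, Olfr1300-ps1 and Btbd35f2, named here after their values were seen, and none had one in iKO (0 of 7, upper limit 41.0%). Promoters held 5.96% of the iKO peaks (95% interval 5.65 to 6.29%) and 0.607% of the Ctrl peaks (0.244 to 1.25%). The iKO list was 18.5 times as long as the Ctrl list. When it was cut to its 1154 peaks of highest score, 41.4% of them lay at promoters. Of the 1154 Ctrl peaks, 14 overlapped an iKO peak (1.21%, 0.665 to 2.03%), against a mean of 4.20 and at most 12 in random placement. With siSCR as the control, an alternative chosen after the data were seen, the iKO list was 8.17 times as long and 992 of its promoter genes were gained.

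Silencing of Seh1 was compared with siSCR. Chd4 was listed at the promoters of 2750 genes in siSeh1 and of 384 in siSCR, and 307 genes were in both (80.0% of the siSCR genes, 75.6 to 83.8%). Gained genes numbered 2443 and lost genes 77. Gained were Hes1, a Notch effector that keeps progenitors undifferentiated (score 17.3), Nup93, a scaffold nucleoporin (13.5), Suz12, a core subunit of Polycomb repressive complex 2 (11.8), Sox2, a stem cell transcription factor (6.86), and Rbbp7, a histone-binding NuRD subunit (8.29). Sox11, a transcription factor of newborn neurons, had the highest promoter score of both lists. That peak lay in its single exon on chromosome 12, at 27342190 in siSCR and 27342018 in siSeh1. With a single exon, Sox11 has no introns to tell binding from the copies of transcripts considered below for exon peaks. In iKO a peak in the same exon lay just outside the promoter window, at 27341558.

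In both lists Chd4 also had promoter peaks at Ezh2, E2f1, E2f3, Aurka, Gatad2a and Mbd3. Within the siSeh1 list, the genes shared with siSCR had a median promoter score of 12.2 and the gained genes 4.58. Of the 100 siSeh1 promoter genes with the highest scores, 71 were also in siSCR. The siSeh1 list was 10.3 times as long as the siSCR list, and 411 of the 2606 siSCR peaks overlapped one of its peaks (15.8%, 14.4 to 17.2%), against a mean of 19.8 in random placement. Promoters held 15% of the siSCR peaks (13.6 to 16.4%) and 10.4% of the siSeh1 peaks (10.1 to 10.8%). This order turned at equal list length, where 53.1% of the 2606 siSeh1 peaks of highest score lay at promoters.

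**Figure D3:**
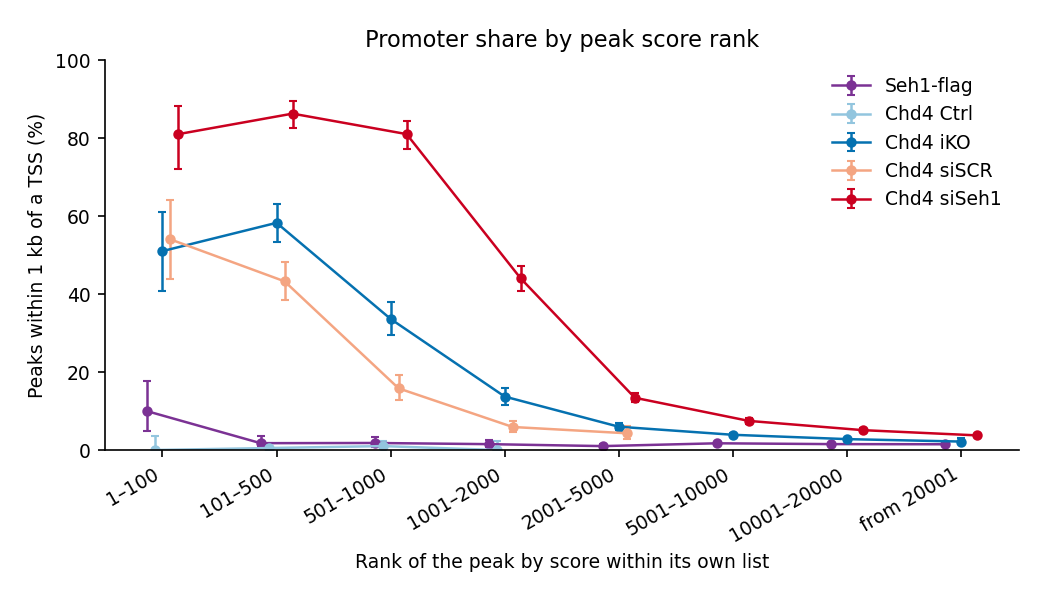
Percent of peaks within 1 kb of a TSS, by the rank of the peak score within its own list, for the 5 lists with scores (points, with exact 95% intervals, counting error only). Among the first 100 peaks the share is 81% in siSeh1, 54% in siSCR, 51% in iKO, 10% in Seh1-flag and 0% in Chd4 Ctrl.

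Chd4 promoter peaks of high score thus stood near the top of 3 of the 4 Chd4 lists. Of the 384 siSCR promoter genes, 253 also had a promoter peak in iKO (65.9%, 60.9 to 70.6%), and 61 of the 100 iKO promoter genes with the highest scores were in siSCR. No gene had a Chd4 promoter peak in both Ctrl and siSCR, and none had one in all 4 Chd4 lists. Over all peaks, 61 of the 1154 Ctrl peaks overlapped a siSCR peak (5.29%, 4.07 to 6.74%), 77.2 times random placement. In siSCR, iKO and siSeh1 together, 234 genes had one.

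Deletion and silencing of Seh1 were set side by side to ask whether Chd4 was gained at the same places. Both gained Chd4 at the promoters of 495 genes. The first of these by rank were Rbm15, which directs RNA methylation (score 19.5 in iKO, 24 in siSeh1), Rrbp1, a ribosome-binding protein of the endoplasmic reticulum (14.5 and 22.1), Mis12, a kinetochore protein (10.9 and 27.2), and Fdft1, squalene synthase (11.3 and 24). They were followed by Cdc25c, a phosphatase that starts mitosis (13.7 and 19.0), Cyld, a deubiquitinase (10.3 and 25.2), Map2k3, a p38 kinase activator (11 and 19.0), Etv5, an ETS transcription factor (17.1 and 15.5), Zfyve21 (11.3 and 17.9) and Stard4, a sterol carrier (14.8 and 15.5). All 10 peaks lay in the annotated promoter in both lists. Rbm15 had its peaks on chromosome 3 at 107333280 in iKO and 107333224 in siSeh1, and Fdft1 on chromosome 14 at 63177978 and 63178023.

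Of the protein-coding genes, 476 were gained in both, against 119 for independent lists of the same sizes. The iKO list shared more than chance with the control siSCR as well: 238 protein-coding promoter genes against 18.5 for independent lists, and 342 siSCR peaks, 19.8 times random placement. Among gained peaks, 727 of the 21280 in iKO overlapped a gained siSeh1 peak (3.42%, 3.18 to 3.67%), against a mean of 118.4 in random placement (6.14 times). The overlap was concentrated at promoters. There 476 of 1270 gained iKO peaks overlapped one (37.5%, 34.8 to 40.2%), and away from promoters 251 of 20010 did (1.25%, 1.10 to 1.42%). With every list cut to the length of the shortest, 180 genes and 251 peaks were gained in both.

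The gene lists showed which groups had Chd4 at their promoters. Of 35 cell cycle genes, 15 had a Chd4 promoter peak in siSeh1, 6 in iKO, 4 in siSCR and 0 in Ctrl. In Ctrl random lists averaged 0.0052, so 0 was the likely count there. Bub1, Mki67 and Ccne1 were gained in both comparisons, and Aurka, E2f1 and E2f3 were in siSCR, iKO and siSeh1. As many members were found in 0 of the 10000 random lists for siSeh1, 0.79% for iKO and 0.26% for siSCR. The random lists came from all protein-coding genes. These shares therefore do not tell cell cycle genes from expressed genes in general. Of 26 genes of chromatin remodelling and Polycomb complexes, 10 had one in siSeh1 (0.04% of random lists), 4 in iKO (4.27%) and 1 in siSCR (35.7%). Suz12, Smarca2 and Actl6a were gained in both comparisons, and Chd8 and Kmt2a in siSeh1. Against the background of genes named in any list the iKO values were 7.4% for this list and 2.55% for the cell cycle genes. Of 15 NuRD members, Gatad2a and Mbd3 were listed in iKO (17.8%) and siSCR (2.16%), and Hdac1, Rbbp4 and Rbbp7 joined them in siSeh1 (2.37%).

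**Figure D4:**
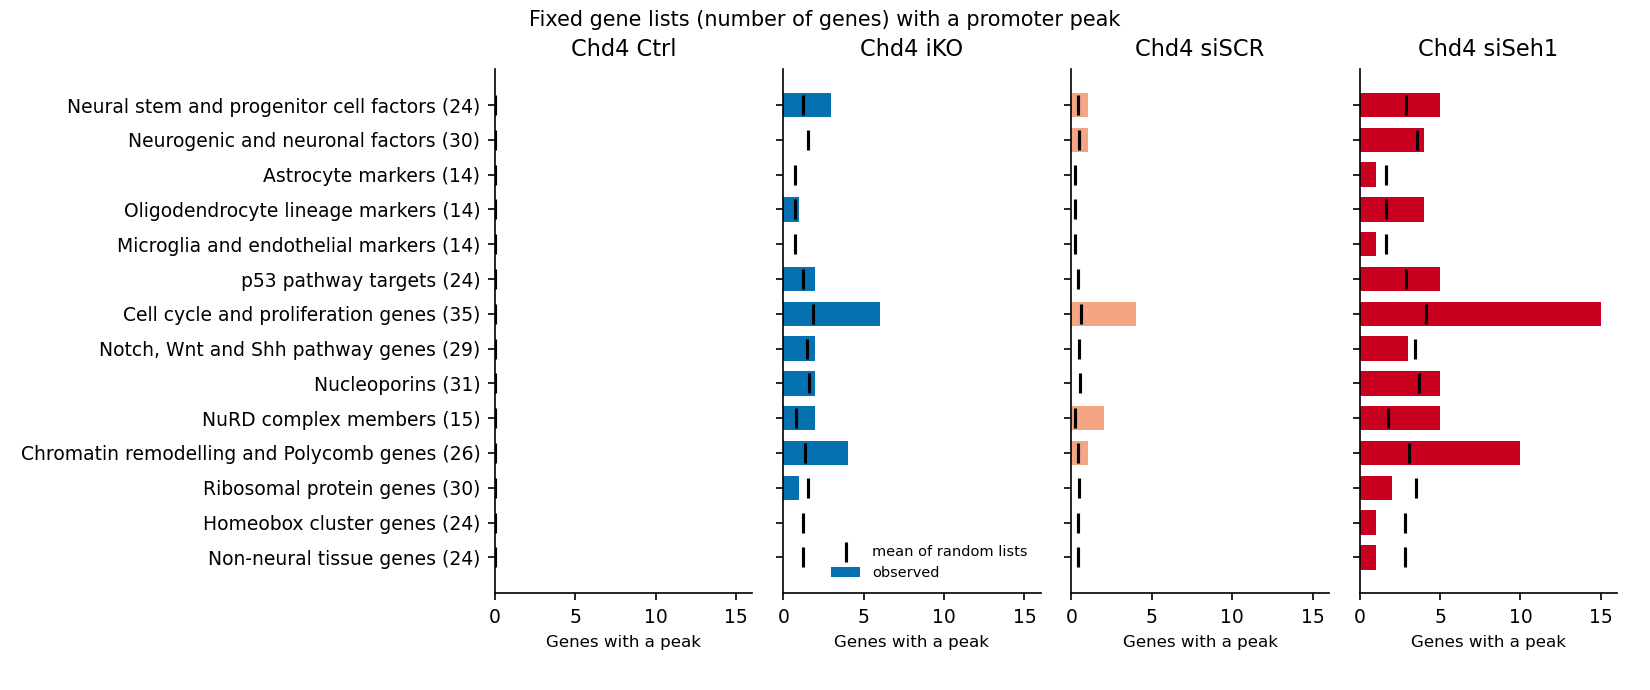
Number of genes of each of 14 lists with a Chd4 promoter peak (bars) in the 4 Chd4 libraries, with the mean of 10000 random lists of the same size (black ticks) and the size of each list in parentheses. Cell cycle genes reach 15 of 35 in siSeh1 against a random mean of 4.15.

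For lists of cell identity and p53 targets at least 7.33% of random lists held as many members in every Chd4 list. Of 24 neural stem cell factors, 5 had a Chd4 promoter peak in siSeh1 (14.6% of random lists) and 3 in iKO (12.9%). Hes1 and Otx1 were gained in both comparisons, and Sox2 and Lhx2 in siSeh1. Of 30 neurogenic and neuronal factors, siSeh1 held Btg2, Hes6, Sox4 and Sox11 (48.1% of random lists) and iKO held 0. Of 14 oligodendrocyte markers, siSeh1 held Olig1, Olig2, Gpr17 and, in an exon, Sox10 (7.33%), and iKO held Olig1 (53%). Of 14 astrocyte markers siSeh1 held Id4, and of 14 microglia and endothelial markers it held Pdgfrb, with 82.4% and 83.2% of random lists holding as many. Of 24 p53 targets, siSeh1 held Aen, Btg2, Mdm2, Rrm2b and Trp53inp1 (14.5%), and iKO held Rrm2b and Sesn1 (35.6%).

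For the other lists at least 29.7% of random lists held as many. Of 31 nucleoporins, Nup50 and Nup93 were gained in both comparisons and siSeh1 held 5 in all (29.7% of random lists), with Nup50 and Nup93 making up the iKO count (48.0%). Of 29 genes of the Notch, Wnt and Shh pathways siSeh1 held Axin2, Ctnnb1 and Hey1 (69%), and iKO held Notch2 and Sufu (45.1%). Of 30 ribosomal protein genes siSeh1 held 2 against a random mean of 3.51, and iKO held 1 against 1.56. Of 24 homeobox cluster genes siSeh1 held Hoxa2, and of 24 genes of other tissues it held Myh6, each against a random mean of 2.83. Promoter peaks of these last lists were absent from iKO.

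The Seh1 lists were compared with each other. Most Seh1 peaks lay away from promoters, which held 1.53% of the Seh1-flag peaks (1.38 to 1.69%) and 1.35% of the Seh1 Ctrl peaks (1.2 to 1.52%). The share that random positions would give was not computed, so no preference is read from these values. Sox11 had the highest Seh1-flag promoter score, 259, in its single exon on chromosome 12 at 27341891, where the limit given above for this gene holds too. Both lists had a promoter peak at 6 genes, B4galt1, a galactosyltransferase, Nrf1, a transcription factor of mitochondrial genes, Proser1, Adam19, Pramel1 and a microRNA gene. At Adam19 the 2 peaks lay at different start sites, at 46053832 and from 46127047 on chromosome 11. At B4galt1, Proser1 and Pramel1 the highest Seh1-flag promoter peak did not overlap that of Seh1 Ctrl either, and at Nrf1 it did. Independent lists would share 2.98 protein-coding genes, and 5 of the shared genes were protein-coding. Of the 20833 Seh1 Ctrl peaks, 176 overlapped a Seh1-flag peak (0.845%, 0.725 to 0.979%), against a mean of 117.7 and at most 153 in random placement. The ratio was 1.496. Against random peaks drawn from the 4 Chd4 lists it turned to 0.694, an alternative chosen after the data were seen. That draw holds Chd4 Ctrl and siSCR, which overlapped Seh1-flag at 21.2 and 10.4 times random placement. It is therefore no measure of chance.

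Seh1 and Chd4 lists were then compared to ask whether both proteins were listed at the same places. Seh1-flag shared 12 protein-coding promoter genes with siSCR (4.76 for independent lists), 18 with iKO (15.1), 32 with siSeh1 (34.4) and 0 with Chd4 Ctrl (0.0532). Seh1 Ctrl shared 3 (3.66), 15 (11.6), 18 (26.5) and 0 (0.0409) in the same order. Of 8 genes gained in both Chd4 comparisons that also had a Seh1 promoter peak, 7 were protein-coding, against 11.1 for independent lists. Suz12, Akap11, Psma3 and Rrm2b had the Seh1 peak in Seh1-flag, and Stmn1, a microtubule regulator of growing neurites, Asf1b, a histone chaperone, and Chpf had it in Seh1 Ctrl. At none of the 7 did the Seh1 peak overlap a gained Chd4 peak: the centres lay 369 to 1284 bp apart, and at Akap11 14800 bp or more, at different start sites. Away from single genes, 121 Seh1-flag peaks overlapped a Chd4 Ctrl peak (0.485% of the Seh1-flag peaks, 0.402 to 0.579%), 21.2 times the mean of random placement, and 178 overlapped a siSCR peak (0.713%, 0.612 to 0.825%), 10.4 times. In iKO and siSeh1 the counts were 181 (0.725%) and 155 (0.621%), 1.60 and 1.13 times. The siSeh1 count lay inside the random range of 107 to 170, and outside dense bins its ratio was 0.916. Against random peaks from the lists not compared, chosen after the data were seen, the ratios were 2.98 in Ctrl, 0.583 in siSCR, 0.232 in iKO and 0.170 in siSeh1. That draw holds the Seh1 Ctrl list and the other Chd4 lists, and the Chd4 lists overlap each other, so it is no measure of chance. None of the 121 overlaps with Chd4 Ctrl lay at a promoter. With siSCR 5 of 178 did, with iKO 4 of 181 and with siSeh1 6 of 155. Sox11 lay outside the 8 genes above because siSCR listed it too and its iKO peak lay outside the promoter window. Its promoter peaks were at 27341891 in Seh1-flag and 27342018 in siSeh1.

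For the Seh1 Ctrl list the numbers were 20 peaks in Chd4 Ctrl (0.096%, 0.0587 to 0.148%), 43 in siSCR (0.206%, 0.149 to 0.278%), 236 in iKO (1.13%, 0.994 to 1.29%) and 216 in siSeh1 (1.04%, 0.904 to 1.18%). These were 3.66, 2.52, 2.18 and 1.65 times random placement, and 0.345, 0.153, 0.401 and 0.320 times the same draw from the lists not compared. Here that draw holds Seh1-flag, which overlapped Chd4 Ctrl at 121 peaks. At promoters lay 8 of the 236 overlaps with iKO, 3 of the 216 with siSeh1 and 0 of those with Chd4 Ctrl or siSCR. Leaving out 43 bins of 200 kb in which Chd4 Ctrl or siSCR peaks were densely packed, chosen after the data were seen, lowered the Seh1-flag share with Chd4 Ctrl to 0.210% and with siSCR to 0.281%.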

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

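Every test in this section was chosen after its result was seen. Exon or untranslated region (UTR) peaks lay in 24 of 40 genes abundant in liver in the iKO list of Chd4. In Ctrl 0 of them had one, where random lists averaged 0.0209. The iKO list held 2 exon peaks in Chd4 and Ctrl 0. The siSeh1 list held 7 exon peaks in Chd4 and siSCR 6. The siSeh1 list held 3 exon peaks in Seh1l and siSCR 1.

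The Chd4 lists were 18.5 times as long in iKO as in Ctrl and 10.3 times as long in siSeh1 as in siSCR. A siSCR list that read the siSeh1 sites with less sensitivity is a candidate for the promoters, where the siSCR genes found in siSeh1 stood at a median percentile of 89.98 of its scores, although a true rise of Chd4 there could give the same. For the list as a whole the overlap could not decide. It held 15.8% (14.4 to 17.2%) of the siSCR peaks, but the long iKO and siSeh1 lists shared only 4.79% of the iKO peaks. At promoters lay 15% of the siSCR peaks, against 53.1% of the 2606 siSeh1 peaks of highest score. A siSCR list made up in large part of background was not tested. A Ctrl list that read the iKO sites with less sensitivity is argued against by the 0.607% of Ctrl peaks at promoters, against 41.4% of the 1154 iKO peaks of highest score, while a Ctrl library with little enrichment was not tested and stays open. That Chd4 reached the iKO promoters only where Seh1 was lowered is argued against for the 253 genes that siSCR also listed, and for the other 992 it cannot be told apart from the shorter control list.

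Exon peaks in the Chd4 libraries were followed in Chd4, Seh1l and genes of other tissues. Binding along transcribed Chd4 and Seh1l is argued against. Of their peaks in the Chd4 libraries, 19 of 21 (90.5%) lay in exons, against 4.26 to 9.78% over all genes in these libraries. The shares over all genes were not matched for exon density. Chd4 has 39 exons, so part of this contrast may come from gene structure. The interval of 69.6 to 98.8% counts these peaks as independent. Chd4 exon 6 was listed in iKO, siSCR and siSeh1, and Seh1l exon 4 in siSCR and siSeh1, so that interval is too narrow. Copies of spliced transcripts, such as complementary DNA or plasmid carried into the libraries, are a candidate explanation of these 19 peaks, and no read data were used here that would show splice junctions. For the liver genes in iKO, spliced liver material is likewise a candidate: without the genes that prompted the list, 7 of 23 (Ahsg, C3, Fgg, Serpina1a, Serpina3k, Tat and Vtn) had an exon or UTR peak, a count reached by 0 of 10000 random lists, although some of them may also have been seen earlier. Copies of the cells' own abundant transcripts stay open, since 6.67% (0.818 to 22.1%) of 30 neural genes had such a peak and 30.4% (13.2 to 52.9%) of these 23 liver genes did, with intervals that overlap.

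The overlap of Seh1-flag with the Chd4 lists of control cells was 21.2 times random placement in Ctrl and 10.4 times in siSCR. The 43 dense bins alone are argued against, because outside them the ratio to random placement was still 12.3 in Ctrl and 6.19 in siSCR. Smaller clusters of peaks and regions dense only in Seh1-flag were not removed. Random placement was not matched for mappability, so regions of that kind stay open. Seh1 and Chd4 at the same places could not be decided: the Seh1 Ctrl list gave 3.88 in Ctrl outside the bins, from 16 peaks. Background shared by the 3 lists with WT in the header name could not be decided either. Outside bins and promoters Chd4 Ctrl with siSCR gave 133.3, Seh1-flag with Chd4 Ctrl 12.2 and Seh1-flag with siSCR 7.44. The highest pair with a list not so named, siSCR with iKO, gave 7.34, but both of these lists target Chd4. Seh1-flag with the lists not so named gave 1.26 for Seh1 Ctrl, 1.48 for iKO and 1.00 for siSeh1.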

How the results depend on the processing

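The settings compared below were fixed before the data were examined, except 4 chosen after the results were seen: siSCR as the control of iKO, leaving out dense bins, leaving out exon peaks, and random peaks drawn from the lists not compared. A count or a ratio was called the same within 1.5 times its main value, a share within its 95% interval, and a difference of shares within its counting error. A change of direction was called reversed. By these rules 53 of 119 settings run on the main results left the value the same, 47 moved it and 19 reversed it. All reversals except that of the siSeh1 promoter share came from draws of random peaks out of the lists. For single gene lists, 69 of 84 counts stayed within 1.5 times with other promoter windows and 15 did not. With the other background, 41 of 42 shares of random lists stayed on the same side of 5% and 1 did not, although values such as 0.79% for the cell cycle genes in iKO, which became 2.55%, moved by more than 1.5 times. The cause was not tested in any case unless a construction is named. No paired analysis was possible because each group has 1 library. Scaling by total tags was not run, since total tags are not in the lists, and score-based settings were not possible for Seh1 Ctrl.

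With siSCR as the control, the iKO list was 8.17 times as long instead of 18.5.

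With 50% of both peaks required to overlap, 8 peaks were shared between Ctrl and iKO and 105 between the Seh1 lists. The Seh1-flag share was 0.389% in Ctrl, 0.533% in iKO, 0.561% in siSCR and 0.401% in siSeh1. The Seh1 Ctrl share was 0.638% in iKO, 0.12% in siSCR and 0.610% in siSeh1. With centres within 500 bp, 269 peaks were shared between the Seh1 lists. The Seh1-flag share was then 0.629% in Ctrl, 1.10% in iKO, 0.925% in siSCR and 1.10% in siSeh1, and the Seh1 Ctrl share 1.53% in iKO and 1.40% in siSeh1. A stricter or looser rule lowers or raises counts by construction.

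With only the 50% of each list with the highest scores, 6 peaks were shared between Ctrl and iKO. The promoter share differed by 8.69 points for iKO and by -8.85 points for siSeh1, against 5.36 and -4.55 with all peaks. The Seh1-flag share in siSCR was 0.905%.

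With the longer list at the length of the shorter, 5 peaks were shared between Ctrl and iKO. The promoter share differed by 40.8 points for iKO. For siSeh1 it differed by 38.1 points, which reversed the direction. With every list at the length of the shortest, 180 genes and 251 peaks were gained in both comparisons, and the Seh1-flag share was 2.08% in Ctrl and 4.14% in siSCR.

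With promoters within 5 kb, the promoter share differed by 7.89 points for iKO. Gained genes were 2474 in iKO and 4054 in siSeh1, and lost genes 36 and 159. Members of the 14 lists with a promoter peak were 41 in Seh1-flag instead of 7, 12 in Seh1 Ctrl instead of 2, 1 in Chd4 Ctrl instead of 0 and 36 in iKO instead of 23. With promoters within 500 bp, 2 genes were lost in iKO, and 1 member was left in Seh1-flag and 0 in Seh1 Ctrl.

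Without dense bins, the Seh1-flag share was 0.210% in Ctrl, 0.557% in iKO, 0.281% in siSCR and 0.462% in siSeh1, and the Seh1 Ctrl share 0.928% in iKO, 0.116% in siSCR and 0.842% in siSeh1.

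With random peaks drawn from the pooled lists, every ratio fell below 1 by construction, since the pool holds the list compared. The ratio was 0.0322 for the Seh1 lists and 0.122 for peaks gained in both. For Seh1-flag it was 0.343 in Ctrl, 0.0307 in iKO, 0.192 in siSCR and 0.0212 in siSeh1, and for Seh1 Ctrl 0.0679 in Ctrl, 0.0480 in iKO, 0.0558 in siSCR and 0.0352 in siSeh1. With random peaks from the lists not compared, the ratio was 0.694 for the Seh1 lists. There the draw holds Chd4 Ctrl and siSCR, which overlap Seh1-flag above random placement, so this value is no measure of chance. For Seh1-flag it was 2.98 in Ctrl, 0.232 in iKO, 0.583 in siSCR and 0.170 in siSeh1, and for Seh1 Ctrl 0.345, 0.401, 0.153 and 0.320 in the same order. All of these fell below 1 except Seh1-flag in Ctrl. For Seh1 with Chd4 this draw holds the other Chd4 lists, which overlap each other (1019 peaks of iKO with siSeh1, 411 of siSCR with siSeh1), so a value below 1 compares Seh1 with Chd4 lists and does not set the excess over random placement aside. For peaks gained in both the ratio was 5.10, but this draw holds siSCR peaks. By definition none of these overlaps a gained siSeh1 peak, which raises the ratio by construction.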

Other observations

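All lists, regions and genes in this section were chosen after the data were seen. Some members prompted each list, and it is not recorded which others had been seen, so each list is also given without the members recorded as having prompted it.

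Cholesterol synthesis enzymes had Chd4 at their promoters in both perturbed lists. Of 20 enzymes, 10 had a promoter peak in iKO, among them Hmgcs1, Sqle, Fdft1 and Idi1, and 17 in siSeh1, among them also Lss and Cyp51. In siSCR 3 had one. Random lists averaged 1.04 in iKO and 2.35 in siSeh1, and 0 of 10000 held as many. Without the prompting members the counts were 6, 13 and 3 of 16 (0, 0 and 0.21% of random lists), for iKO, siSeh1 and siSCR.

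Chaperones of the endoplasmic reticulum stood out in 3 of the 4 Chd4 lists. Of 22 genes, 14 had a promoter peak in iKO, 16 in siSeh1 and 10 in siSCR. Hspa5, the main chaperone of this compartment, Dnajb9, Dnajc3, Pdia4 and Sdf2l1 were in all 3. Without the prompting members the counts were 11, 14 and 8 of 19, each reached by 0 of 10000 random lists.

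Genes of centrioles and microcephaly had 6 of 29 members with a promoter peak in iKO, 11 in siSeh1 and 2 in siSCR. Aspm, Cenpe, Cep152, Pcnt, Stil and Wdr62 were in both perturbed lists. Without the prompting members 4 of 27 were left in iKO (4.79% of random lists), 9 in siSeh1 (0.23%) and 2 in siSCR (7.48%). All 3 groups had 0 promoter peaks in Chd4 Ctrl and in both Seh1 lists. Random lists averaged 0.0029 to 0.0049 in Chd4 Ctrl and 0.203 to 0.392 in the Seh1 lists, so 0 was the likely count there. In introns, 12 of the 29 centriole and microcephaly genes had a peak in Seh1-flag (1.28% of random lists) and 12 in Seh1 Ctrl (0.19%), and without the prompting members 11 of 27 in each (1.76 and 0.43%). The random lists were not matched for gene length.

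In the iKO list the highest peak score of all, 49.8, was in an exon of Apoe, and Hp, haptoglobin, stood at rank 5 with 29.8. Alb, albumin, had peaks in exons 4, 8 and 12. The 40 liver genes held 33 exon or UTR peaks and 4 intron peaks. Apoe, Trf and Ttr are also made in brain. Other groups had few such peaks in iKO: 2 of 30 muscle genes (18.2% of random lists), 1 of 29 pancreas genes (52.4%) and 3 of the 24 genes of other tissues (2.49%), of which Alb and Apoa1 are liver genes. In siSeh1, 2 liver genes had one (41.8%), and in siSCR 0.

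Robo2, an axon guidance receptor, had 5 exon peaks and 12 intron peaks in Seh1-flag, the highest at rank 17 in exon 1 with a score of 33.3. Seh1 Ctrl held 15 intron peaks there and 0 in exons.

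Simple repeats held 9.75% of the Seh1-flag peaks (9.38 to 10.1%), against 1.31 to 2.08% in the other lists. Short interspersed elements held 15.1% of them (14.6 to 15.5%), against 3.81 to 7.29%. The X chromosome held 23.7% of the Chd4 Ctrl peaks (21.3 to 26.3%), against 7.47% in Seh1 Ctrl, 5.59% in siSeh1, 5.07% in iKO, 4.72% in Seh1-flag and 4.07% in siSCR. The 43 dense bins were picked for holding 5 or more Chd4 Ctrl or siSCR peaks, so the high shares of these lists follow from the choice. In them lay 20.5% of the Chd4 Ctrl peaks (18.2 to 22.9%), 12.6% of the siSCR peaks (11.4 to 14%), 2.91% of the Seh1-flag peaks and at most 1.0% of the other lists. Outside these bins the X chromosome still held 13.7% of the Chd4 Ctrl peaks. A bin on chromosome 4 from 122000001 to 122200000 held 22 Seh1-flag, 20 Chd4 Ctrl and 23 siSCR peaks, 4 in iKO and 0 in siSeh1 and Seh1 Ctrl.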
